A study of Caenorhabditis elegans with 2 samples.

How the data were processed

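The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of ZTF-6, a C2H2 zinc finger protein, in the nematode Caenorhabditis elegans. Per the labels, the gene had been edited with CRISPR so that the protein carried an EGFP tag, and the precipitation used an antibody against GFP. Per the labels, whole young adult animals of age 62 hours were used, grown from larvae synchronised by starvation, and the chromatin had been sonicated to fragments of 200 to 800 bp. The labels name 2 biological replicates of this single group and no second condition, so the comparisons are between the replicates, between binding sites and random positions, and between groups of genes.

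The analysis started from the peak lists the authors deposited. Per the labels, positions are on the ce11 assembly. The file lists deposited with each sample state that peaks were derived from filtered alignments and a control alignment file; the aligner, the peak caller and their versions are not given in the sources used here. For each replicate, and for the replicates together, the authors deposited a ranked list and a shorter thresholded list. The score column of the deposited lists is a whole number scaled from the irreproducible discovery rate (IDR), up to 1000. The signal value is the peak's own signal as the authors' caller gave it over the control, on a scale that is not given in the sources used here. The authors' q-value and IDR columns are deposited as −log10 values. Signal values were used only to describe and rank peaks within a list and to correlate the replicates.

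Testing the files showed that every thresholded peak had an IDR of at most 0.01 in its ranked list. An alternative planned at an IDR of 0.01 was therefore the authors' own threshold and gave no separate value. Some peaks at or under 0.01 were missing from the thresholded lists, which, per the deposited file lists, also derive from a further annotation file. That file was not used here. The conservative thresholded list of the series, which rests on the comparison of the replicates, was the main list.

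Read counts and sequencing depth are unknown from these lists, so no counting interval was computed for any peak's signal. Intervals at the 95% level for shares of peaks or genes are exact binomial (Clopper-Pearson) intervals. They cover counting error only, not the spread between animals. Odds ratios of gene lists have 0.5 added to each count and normal intervals on the log scale.

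Genes and transcripts were taken from Ensembl release 115 and sequence from the RefSeq copy of WBcel235, whose coordinates are those of ce11. All peaks of the lists used lay within the lengths of its 6 nuclear chromosomes. A gene was counted as carrying a peak when a summit lay within 500 bp of an annotated transcript start. A peak near several starts counted for each of those genes. The share of summits near starts was compared with 1000 random placements within the same chromosomes, one-sided. Annotation classes were compared with 1000 random placements, two-sided, with Benjamini-Hochberg adjustment. Chromosome shares were compared with chromosome length and with the share of protein-coding genes by exact binomial tests, two-sided and adjusted over the 6 chromosomes.

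Gene lists were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 33 lists. Lists of protein-coding genes were set against all other protein-coding genes and non-coding biotypes against all other genes. The lists were taken from gene symbols, from annotated biotypes or from named tissue markers. The shares of windows of 50 bp each side of the summits holding each of 2080 6-base words, read on both strands, were compared with 10 windows per peak. Those windows lay at the same distance from starts of genes of the same biotype and over 1000 bp from the summit of any peak of the thresholded lists and of any peak at an IDR of at most 0.01. Fisher's exact test with Benjamini-Hochberg adjustment was used, over all words, or over the list alone for 10 words fixed before the data were examined. GC content was compared by a two-sided permutation test with 100000 resamples.

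Replicate lists were compared by overlap of at least 1 bp, with 1000 random placements of the shorter list. Signal at shared sites was compared on a log2 scale with 100000 permutations of the pairs. The text names the 20 peaks with the highest signal and, for each gene list past the threshold, up to 4 members with the highest signal. For other lists that held a peak it names up to 2. It also names ztf-6, the 5 enriched words with the smallest adjusted p, the fixed words and any of 10 well studied genes with a peak. These rules, the lists and the tests were fixed before the data were examined.

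The tests were tested on simulated data over the 19973 protein-coding genes, with 551 peaks in each of 10 runs. Of 50 gene lists with planted peaks (16 of 80 genes), 50 were recovered, and 2 of 150 unplanted lists were called. These lists were drawn at random, so the rates do not carry over to shorter lists or to lists whose genes share peaks. Of 50 words planted in 10% of the windows, 49 were recovered, and at most 1 word per run was called without planting. The simulated windows lay near randomly drawn starts. The rate without planting therefore does not carry over to peaks that differ from their background in GC content. Random summits gave p under 0.05 for proximity to starts in 1 of 10 runs.

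The alternatives covered each replicate's list alone, the other thresholded list of the series, other IDR thresholds, other windows and overlaps, other backgrounds, and lists without peaks on multi-copy RNA genes. Families of similar sequence were found by aligning windows of 100 bp each side of the summits with blastn, at an expectation value of at most 1e-10. For a check of the enriched words, chosen after the data were seen, words were picked on chromosomes I to III and looked up on IV, V and X, with the strongest peak of each family. GC content of family copies was compared by permuting the peak marks within families 10000 times. Repeated sequence was measured as the share of 31-base words that occur more than once in the nuclear genome. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, networkx 3.6.1 and matplotlib 3.10.9, and BLAST 2.17.0.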

Results

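ZTF-6 binding was mapped in whole young adult C. elegans (62 hours) that carried the protein with an EGFP tag. ChIP-seq with an antibody against GFP was done in 2 biological replicates of this single group. The authors' conservative list held 551 reproducible binding sites, or peaks, across the 6 nuclear chromosomes. It covered 0.149% of the genome. A second thresholded list of the series held 605 peaks, of which 460 (76.0%) overlapped a peak of the conservative list. The replicates alone gave 215 and 253 peaks. Sequencing depth is unknown from the peak lists, so the precision behind each signal value cannot be given. The authors' signal values in the conservative list ranged from 2.56 to 443.5, with a median of 85.7. By the authors' q-values, 221 of the 551 peaks (40.1%) were at or under 0.05, and the smallest q was 0.0196. The replicates differed on this measure: 136 of the 215 peaks of replicate 1 (63.3%) were at or under 0.05, against 1 of the 253 of replicate 2 (0.395%).

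The first comparison asked how far the replicates named the same sites. Replicate 1 and replicate 2 shared sites such as those upstream of the ribosomal protein genes rpl-3 and rpl-15 and of mog-4. The authors' signal at rpl-3 was 246.2 in replicate 1 and 208.2 in replicate 2. At mog-4, which encodes a DEAH-box helicase, it was 175.9 and 181.9. Of the 215 peaks of replicate 1, 114 (53.0%) were overlapped by a peak of replicate 2. Random placement gave 0.110% ± 0.228 (SD over 1000 placements), and the one-sided permutation p was 0.001, the smallest these placements can give. In the other direction 113 of 253 peaks (44.7%) were shared. Among the 101 sites of replicate 1 alone, 96 (95.05%) had a peak in the unthresholded ranked list of replicate 2, at a median signal percentile of 97.9 in that list. The corresponding values for the 140 sites of replicate 2 alone were 129 (92.1%) and a percentile of 97.1. The ranked lists covered 12.4% and 12.2% of the genome.

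Sites with high signal in replicate 1 also had high signal in replicate 2. Across the 114 shared sites, which are not independent replicates, Spearman's rho was 0.552 and Pearson's r of the log2 signal was 0.695. Each had a permutation p of 1e-05, the smallest that 100000 permutations can give. Without the 2 sites farthest from the replicate 1 median, rho was 0.530 and r was 0.690. Over all 21042 overlapping sites of the ranked lists, rho fell to 0.246.

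**Figure D1:**
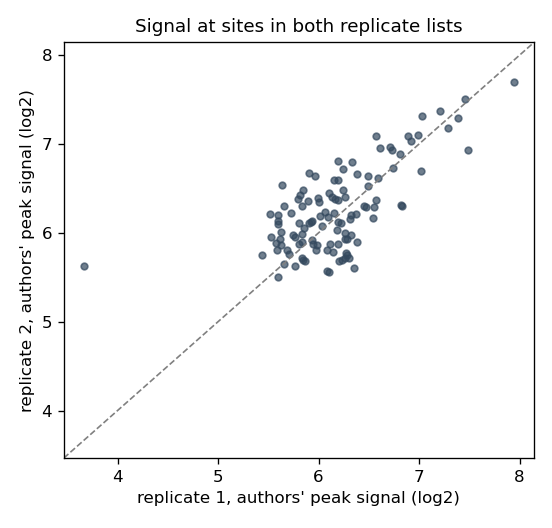
Each point is a site present in both replicate lists (114 sites); the axes give the authors' peak signal in replicate 1 and in replicate 2 as log2 values, and the dashed line marks equal signal. The points rise together, with a Spearman's rho of 0.552.

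The 20 strongest sites of the conservative list included 4 upstream of ribosomal protein genes. Peaks with up to 3566.2 passed the authors' IDR threshold but are missing from that list, 7 of them stronger than any peak in it. The peak with the highest signal in the list (443.5; chromosome III, 3867473 to 3867682) had its summit 272 bp upstream of rpl-3 (WBGene00004414), which encodes a protein of the large ribosomal subunit. Further ribosomal protein genes among the 20 strongest peaks were rpl-15 (signal 324.7, summit 356 bp upstream), rpl-20 (233.8, 297 bp upstream) and rpl-35 (231.9, 445 bp upstream). The rpl-15 peak also lay 458 bp upstream of K11H12.8, and the rpl-20 peak 165 bp upstream of Y17G9B.5. The second strongest peak (360.7; chromosome II, 14561770 to 14561952) lay 272 bp upstream of mog-4 (WBGene00003392). Others lay 60 bp upstream of tasp-1 (321.9), 155 bp upstream of cdc-48.1 (246.9), an AAA ATPase gene, and 368 bp upstream of eel-1 (219.8), a ubiquitin ligase gene. In a grouping chosen after the data were seen, 9 of the 20 peaks, among them those at mog-4 and eel-1, belonged to families of similar sequence other than families of tRNA, snoRNA or snRNA genes.

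Small RNA genes and pseudogenes accounted for further peaks of these 20. A peak with signal 261.8 (chromosome I, 10517166 to 10517303) lay 81 bp upstream of the snoRNA gene F59C6.15 and 281 bp upstream of the ncRNA gene F59C6.19. The cdc-48.1 peak also lay 498 bp upstream of the snoRNA gene C06A1.9. A peak with signal 192.2 on chromosome X (3035979 to 3036258) lay 45 and 72 bp upstream of the tRNA genes WBGene00023110 and WBGene00023111, and its summit lay 155 bp downstream of the start of the ncRNA gene M02F4.12. On chromosome IV, peaks with signals of 312.4 and 295.3 lay 75 bp upstream of the pseudogene WBGene00023323 and 118 bp upstream of the ncRNA gene WBGene00195021, 426 bp downstream of the start of K08F11.1. The other 8 had no transcript start within 500 bp of the summit, or only that of the piRNA gene 21ur-15381 (192.3, 355 bp). Their nearest genes were M04F3.7 (300.96, 579 bp), K12H4.5 (252.6, 530 bp), Y62F5A.12 (246.5, 523 bp), the pseudogene WBGene00023318 (233.2, 1076 bp), ccm-2 (228.0, 3244 bp), fbxa-190 (215.6, 3301 bp) and linc-128 (193.5, 589 bp).

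No peak of the thresholded lists lay within 2000 bp of ztf-6 itself (WBGene00012317; chromosome I, 11206922 to 11211905, plus strand), the tagged gene. In the ranked list behind the conservative list, 14 peaks lay there, with a highest signal of 33.6 and a smallest IDR of 0.380. None of the 10 well studied genes looked up had a peak (unc-119, hlh-1, elt-2, pgl-1, pha-4, lin-39, mab-5, egl-5, lin-14 and daf-16).

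Binding sites lay mostly in the regions upstream of genes. Of the 551 summits, 384 (69.7%) were within 500 bp of a transcript start of any gene, against 33.1% ± 1.97 (SD over 1000 random placements), or 2.10-fold the random share. The one-sided permutation p was 0.001, the smallest possible here. For protein-coding transcripts alone the share was 42.5%, against 22.7% ± 1.78. Of the 234 summits within 500 bp of a protein-coding start nearest to them, 193 lay upstream (82.5%, exact 95% interval 77.0 to 87.1) and 41 downstream. Among random positions 48.2% lay upstream (exact binomial p = 1.8e-27). The bin with the most summits was 200 to 300 bp upstream of the start, with 51 peaks.

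**Figure D2:**
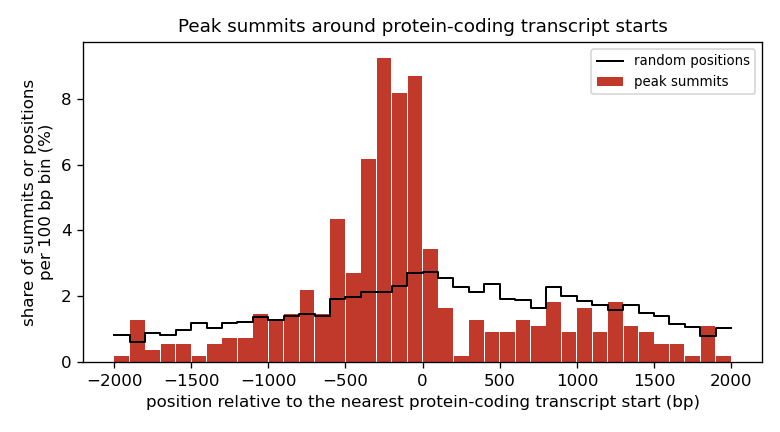
Share of the 551 peak summits (bars) and of random positions (line) in bins of 100 bp by position relative to the nearest protein-coding transcript start, with negative positions upstream. The bars stand above the line from 600 bp upstream to the start, and below it from 100 to 500 bp downstream.

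Upstream regions of 500 bp held 298 summits (54.1%, against 19.2% ± 1.59 at random; adjusted permutation p = 0.0035, from the smallest raw p these placements can give). Exons of non-coding genes held 56 (10.2%, against 2.45% ± 0.660; same p). Coding exons held 23 summits (4.17%, against 22.04% ± 1.72) and introns 48 (8.71%, against 29.7% ± 1.97), each below the random share at the same p. In the replicate lists coding exons held 1.98% without replicate 1 and 2.79% without replicate 2, with the call kept. The 3' UTRs held 5 (0.907%, against 2.69% ± 0.722; adjusted permutation p = 0.011). Without replicate 1 they held 0% (against 2.67% ± 1.03, adjusted permutation p = 0.0056). Without replicate 2 they held 0.465% (against 2.60% ± 1.06), and the call was lost (adjusted permutation p = 0.053). The 5' UTRs with 10 summits (1.81%, against 1.2004% ± 0.468) and intergenic sequence with 111 (20.1%, against 22.6% ± 1.76) did not pass the threshold (adjusted permutation p = 0.24 and 0.19).

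The sites were unevenly spread over the chromosomes. Chromosome III carried 103 peaks (18.7%), above its 13.7% of the genome length (exact binomial test, adjusted p = 0.0038) and its 13.2% of protein-coding genes (adjusted p = 0.00064). Both calls were lost in the lists of single replicates, at 16.996% without replicate 1 (adjusted exact p = 0.29 for length and 0.16 for genes) and 16.3% without replicate 2 (adjusted exact p = 0.57 and 0.38). Chromosome V carried 72 (13.1%), below its 20.9% of the length (adjusted exact p = 1.7e-05) and 25.004% of the genes (adjusted p = 3.3e-11). Chromosome X carried 114 (20.7%), which did not pass the threshold against its length (17.7%, adjusted exact p = 0.13) and was above its 13.7% of the genes (adjusted p = 2.1e-05). Without peaks on multi-copy RNA genes, X carried 77 peaks (18.4%), closer to its share of the genes (adjusted exact p = 0.014). The calls on III and V were kept in that run. Chromosomes I, II and IV, with 89, 84 and 89 peaks, passed neither test. The middle 50% of each chromosome's length held 305 peaks (55.4%), against 55.3% of the protein-coding genes (exact binomial p = 1) and 50% of the length (exact binomial p = 0.013). By chromosome this share ran from 43.8% on IV to 76.4% on V.

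Cytosolic ribosomal protein genes carried peaks more often than other protein-coding genes. Of 81 cytosolic ribosomal protein genes, 18 (22.2%, exact 95% interval 13.7 to 32.8) had a summit within 500 bp of a start, against 1.38% of the other protein-coding genes. The odds ratio was 20.8 (95% interval 12.2 to 35.4; Fisher's exact test, adjusted p = 9.1e-16). The strongest were rpl-3, rpl-15, rpl-20 and rpl-35, given above. Of the 19 peaks, 18 lay upstream, at a median position of −294 bp. The share was 6.17% at a window of 200 bp and 11.1% with nearest starts only, and the call was kept in both. Among translation factors 4 of 33 (12.1%) had a peak: iff-2 (signal 177.6), eef-1G (96.9), eef-1A.2 (95.1) and eif-3.C (84.1), with adjusted exact p = 0.0043. Respiratory chain genes had 6 of 37 (16.2%, adjusted exact p = 5.4e-05), among them the cytochrome c oxidase subunit genes cox-5A (141.1), cox-5B (127.5) and cox-6B (82.9) and the ATP synthase gene atp-1 (105.5). The respiratory chain share was 8.11% without replicate 1, at 200 bp, at an IDR of 0.001 and with nearest starts only, and the call was kept in each. Heat shock genes had 3 of 22 (13.6%, adjusted exact p = 0.012), the chaperone genes hsp-1 (162.2), hsp-3 (128.3) and hsp-90 (93.1). The call for translation factors was lost without replicate 1 (6.06%, adjusted p = 0.066), at a window of 200 bp (adjusted p = 0.061), at an IDR of 0.001 (adjusted p = 0.37) and when bound marks were rotated along the gene order (adjusted permutation p = 0.059). Their odds ratio was 10.4 (95% interval 3.83 to 28.2) in the main list, 11.4 (3.12 to 41.9) both without replicate 1 and at 200 bp, and 9.80 (1.88 to 50.98) at an IDR of 0.001, with 2, 2 and 1 bound genes in these 3 runs. That for heat shock genes was lost at 200 bp (adjusted exact p = 0.34) and with nearest starts only (adjusted p = 0.058), with odds ratios of 9.98 and 13.9, against 12.2 in the main list.

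Genes of tRNA, snoRNA and snRNA were also bound more often than other genes. The lists are not independent, since some shared peaks. Those at rps-12, rpl-7A and rps-26 and the weaker peak at rps-23 (76.3) also counted for snoRNA genes. The genes rpl-36.A and nuo-1, the latter of the respiratory chain, had the same peak. Peaks lay at 99 of 612 tRNA genes (16.2%, exact 95% interval 13.3 to 19.3), against 1.21% of other genes, with an adjusted p of 1.0e-72 (Fisher's exact test). These were WBGene00023110 and WBGene00023111 (192.2), WBGene00000308 (170.4) and WBGene00023062 (135.7), followed by 95 others. The 99 genes had 84 peaks, so some neighbours shared a peak, while Fisher's test treats genes as independent. With bound marks rotated along the gene order, 12.1 ± 3.69 (SD) bound tRNA genes were expected (adjusted permutation p = 0.0082). The snoRNA, snRNA, ribosomal protein, respiratory chain, chemoreceptor and pseudogene lists had the same adjusted permutation p. Peaks lay at 45 of 346 snoRNA genes (13.0%, adjusted exact p = 1.5e-28), led by F59C6.15 (261.8), C06A1.9 (246.9) and C51F7.3 and C51F7.4 (both 183.8). Among genes annotated as snRNA, 17 of 129 had a peak (13.2%, adjusted exact p = 2.8e-11), with the SL2 trans-spliced leader genes sls-2.1 (179.0), sls-2.4 (132.1) and sls-2.9 (111.4) first. In the shorter lists of single replicates fewer of these genes had a peak: the shares without replicate 1 were 9.31% for tRNA, 9.25% for snoRNA and 2.33% for snRNA, and without replicate 2 they were 4.08%, 4.62% and 3.88%. The snRNA call was lost without replicate 1 (adjusted exact p = 0.18) and at an IDR of 0.001 (adjusted p = 0.31).

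Of 7958 ncRNA or lincRNA genes, 175 (2.20%) had a peak, against 1.24% of other genes (Fisher's exact test, adjusted p = 2.0e-09). The 38932 other genes include the 15363 piRNA genes, of which 16 (0.104%) had a peak, and these lower the share of other genes. The strongest were WBGene00195021 (295.3), F59C6.19 (261.8), M02F4.12 (192.2) and F26F4.14 (186.9). The share was 1.16% without replicate 1 and 0.729% without replicate 2, and the call was kept in both. It was lost with the nearest start only (0.804%, adjusted p = 1.0), with rotated marks (adjusted permutation p = 0.13) and with genes that have a ranked peak as background (adjusted p = 0.060).

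Chemoreceptor genes, which act in sensory neurons, stood at the other end. Only sri-5 (signal 92.8) of 1364 had a peak (0.0733%), against 1.56% of other protein-coding genes (Fisher's exact test, adjusted p = 1.5e-07). Of 322 F-box genes 0 had a peak (upper 95% limit 1.14%; adjusted exact p = 0.045). piRNA genes had 16 of 15363 (0.104%, adjusted exact p = 2.8e-86), led by 21ur-15381 (192.3), 21ur-13751 (125.6), 21ur-12279 (105.5) and 21ur-14704 (99.4). These 16 genes had 12 peaks, so they are not independent in Fisher's test. With rotated marks, 93.7 ± 15.2 (SD) bound piRNA genes were expected (adjusted permutation p = 0.0082). The 21ur-12279 peak was also that of atp-1, and the 21ur-14704 peak also counted for sup-39, a gene annotated as snRNA. Pseudogenes had 9 of 2128 (0.423%, adjusted exact p = 4.5e-05), led by WBGene00023323 (312.4), WBGene00235319 (128.6), WBGene00014738 (91.9) and WBGene00023260 (88.2). No chemoreceptor gene had a peak in either replicate list alone (0 of 1364 in each), and the call was kept in both. The F-box call was lost under 7 of 12 alternatives, with the share at 0% in each of the 7. The adjusted exact p was 0.060 to 0.97 in 6 of them, and the adjusted permutation p was 0.13 with rotated marks. Without replicate 1 and without replicate 2 the shares were 0.0325% and 0.0260% for piRNA genes and 0.141% in both for pseudogenes, with the calls kept. The pseudogene call was lost with nearest starts only (adjusted exact p = 0.076).

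The other 21 lists did not pass the threshold. Histone genes had 4 of 72 (5.56%, adjusted exact p = 0.054), with his-37 (155.3) and his-67 (92.2) first. They passed the threshold under 5 of 12 alternatives, with adjusted exact p from 0.0087 to 0.046. Without replicate 2, 1 of 72 had a peak (1.39%, adjusted exact p = 0.90). Aminoacyl-tRNA synthetase genes had 2 of 32, ears-2 (85.2) and yars-2 (79.1), and splicing genes had 2 of 31, snr-1 (87.3) and snr-4 (82.5). The splicing list passed without replicate 2 (adjusted exact p = 0.049), in the other thresholded list (adjusted exact p = 0.0035) and at an IDR of 0.05 (adjusted exact p = 0.023). Without replicate 1 it had 1 of 31 (3.23%, adjusted exact p = 0.40), and 0 of 31 at an IDR of 0.001, at a window of 200 bp and with nearest starts only. The synthetase list passed in the other thresholded list (3 of 32, 9.38%, adjusted exact p = 0.031) and had 0 of 32 in each replicate list alone and at an IDR of 0.001. miRNA genes had 4 of 261, with cel-mir-54 and cel-mir-55 (both 95.5) first, 4 of 261 without replicate 1, and 0 of 261 without replicate 2, at an IDR of 0.001 and with nearest starts only. A single bound gene was found among mitochondrial ribosomal proteins (mrpl-55, 65.9), collagens (col-85, 114.6), nuclear hormone receptors (nhr-47, 101.03), other ztf zinc finger genes (ztf-7, 79.996), C-type lectins (clec-126, 110.8) and cell cycle genes (pcn-1, 113.9). The neuron markers gave unc-31 (57.5) and the body muscle markers mlc-1 (67.5). Of these 8 lists, those of mitochondrial ribosomal proteins, ztf genes, neuron markers and muscle markers had no bound gene in either replicate list, and those of nuclear hormone receptors and cell cycle genes had none without replicate 2. The col-85 and clec-126 peaks also counted for tRNA genes, and the unc-31 and snr-4 peaks for genes annotated as snRNA. Those at nhr-47 and ztf-7 also counted for genes of the ncRNA or lincRNA list. No peak lay at the markers of the germ line (0 of 34, upper 95% limit 10.3%), intestine (0 of 22), hypodermis (0 of 19) or pharynx (0 of 14). The same held for proteasome (0 of 33), homeobox (0 of 63), cytochrome P450 (0 of 74), major sperm protein (0 of 31) and rRNA genes (0 of 20). With the peaks missing from the thresholded list put back, 2 of 20 rRNA genes had a peak (adjusted exact p = 0.076).

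**Figure D3:**
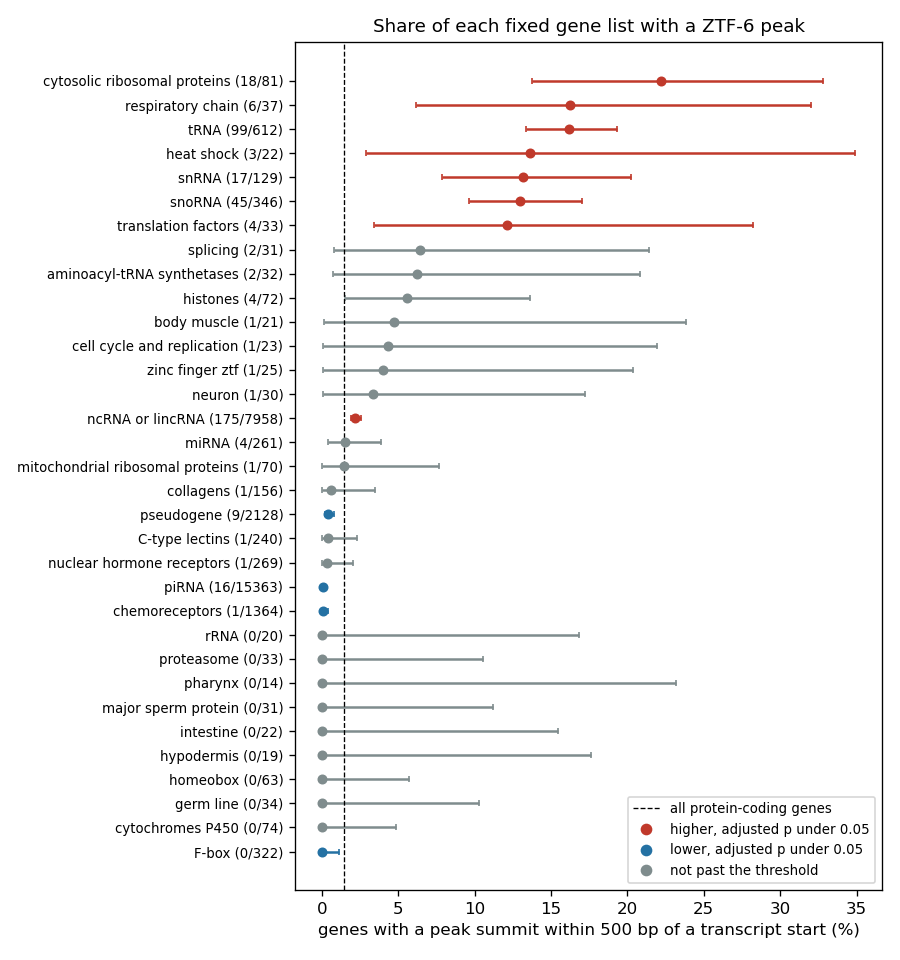
Share of the genes of each of the 33 fixed lists with a peak summit within 500 bp of a transcript start (points, with exact 95% intervals; bound and total genes in brackets). Red and blue mark lists above and below other genes at an adjusted exact p under 0.05, grey the rest, and the dashed line the 1.46% of all protein-coding genes. Cytosolic ribosomal protein genes stand highest at 22.2%, and 0 of 322 F-box genes carried a peak.

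Short GC-rich words marked the sites. In windows of 50 bp each side of the summits, GCGCAC was found in 13.8% of peaks, against 1.54% of windows matched for distance to starts (Fisher's exact test, adjusted p = 1.4e-34). The next words were GCGCGC (11.3% against 1.13%, adjusted exact p = 9.1e-30), GAGCGC (14.9% against 2.45%, adjusted p = 2.4e-29), CGCGCA (12.7% against 1.91%, adjusted p = 1.4e-26) and CGAGAG (15.2% against 3.68%, adjusted p = 1.6e-21). At least 1 of these 5 words was present in 243 of 551 peak windows (44.1%, exact 95% interval 39.9 to 48.4) and in 8.98% of the matched windows. These 5 words were chosen within 50 bp of these same summits, so this share restates that choice. Of the 2080 words, 469 were more frequent and 359 less frequent in peaks.

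Mean GC content of the peak windows was 50.3% ± 7.95 (SD, 551 windows), against 38.1% ± 9.66 in the 5510 matched windows. The permutation p was 1e-05, the smallest possible here. When matched windows were also drawn by GC content, which brought them to 47.1%, 153 words were more frequent. The 5 named words were among them, with smaller differences: GCGCAC stood at 13.8% against 3.97%, GCGCGC at 11.3% against 3.36%, GAGCGC at 14.9% against 4.19%, CGCGCA at 12.7% against 3.81% and CGAGAG at 15.2% against 6.66%.

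Of the 10 fixed words, 5 were more frequent in peaks, adjusted over the list alone by Fisher's exact test. These were CGCG (45.6% against 14.95%, adjusted exact p = 1.0e-56), GCGCGC (adjusted p = 4.4e-32), GAGAGA (17.97% against 7.48%, adjusted p = 1.1e-13), the E-box CACGTG (4.90% against 1.198%, adjusted p = 5.1e-08) and GTGACG (4.36% against 2.16%, adjusted p = 0.0036). The GATA factor word TGATAA (3.09% against 9.29%, adjusted exact p = 8.6e-08), the TATA box word TATAAA (5.08% against 10.6%, adjusted p = 2.1e-05) and the splice acceptor word TTTCAG (6.53% against 16.1%, adjusted p = 2.5e-10) were less frequent. With GC-matched windows the calls for GTGACG (4.36% against 3.63%, adjusted exact p = 0.45) and TATAAA (5.08% against 4.52%, adjusted exact p = 0.52) were lost, and TATAAA turned direction. That for GTGACG was also lost against the flanks of the same peaks (4.36% against 2.54%, adjusted exact p = 0.065), a background of 1102 windows. TGGGAA and CAGGTA did not pass the threshold (adjusted exact p = 0.20 and 0.88).

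Words chosen on one set of chromosomes were then looked up on the others, a test chosen after the data were seen. With 1 peak per family of similar sequence, the 5 words with the smallest p among the 213 peaks of chromosomes I to III were GCGCGC, GCGCAC, AGCGCG, GAGCGC and GCGCCA. At least 1 of them was present in 80 of the 205 peaks of chromosomes IV, V and X (39.0%, exact 95% interval 32.3 to 46.1). The share was 6.24% in distance-matched windows (Fisher's exact test, two-sided p = 1.3e-35) and 15.4% in windows matched on GC content as well (exact p = 1.4e-14).

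**Figure D4:**
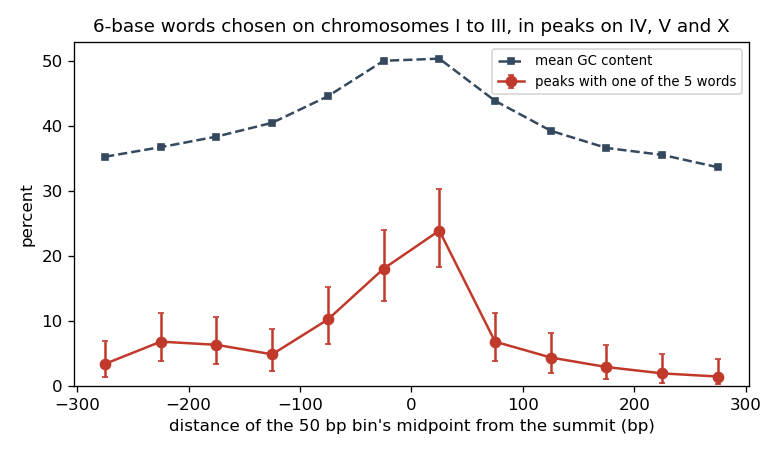
Share of the 205 peaks of chromosomes IV, V and X with at least 1 of the 5 words chosen on chromosomes I to III (points, with exact 95% intervals) and their mean GC content (squares), both in percent, in bins of 50 bp by distance from the summit. Both are highest in the bin from 0 to 50 bp in genome coordinates, at 23.9% and 50.3%.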

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

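A signal stood outside the lists that the report compares: peaks that passed the authors' IDR of 0.01 between the replicates but are missing from their thresholded list. There were 77 of them among 628 (12.3%), and they held 9 of the 10 peaks with the highest signal. The strongest (chromosome X, 15810945 to 15811214) had a signal of 3566.2, against 443.5 for the strongest peak of the list, and 7 exceeded that value. The tests of this pattern were fixed before its values were seen, except the share near transcript starts, which was chosen afterwards; the share of soft-masked bases (85.5%, against 24.5% in the kept peaks) had also been seen before the test of repeated sequence was written.

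Binding at gene starts was argued against: 7.79% of the removed peaks lay within 500 bp of a start, below the random share of 34.6% ± 5.62 (SD over 1000 placements). The random positions were not matched for repeated sequence, so this low share cannot be told apart from the position of repeats. It does not bear on binding away from starts. Repeated sequence is a candidate explanation that the values bear out, though the soft-masked share seen beforehand already pointed to it. The further annotation file behind the thresholded lists was not used, so the rule by which peaks were removed is unknown here. Among the removed peaks the median share of 31-base words that occur more than once in the genome was 93.0%, against 0% in the kept peaks. The means were 87.4% ± 15.7 (SD) and 15.6% ± 25.04 (two-sided permutation p = 1e-05, the smallest possible here). Apart from binding at gene starts, no biological explanation was tested, since the design has no second group.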

How the results depend on the processing

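The IDR thresholds of 0.001 and 0.05, dropped neighbours, restored peaks, rotated marks, GC-matched windows, 1 peak per sequence family, word and GC tests without multi-copy genes, and the runs of chromosomes, annotation and GC content by replicate were chosen after the data were seen. The planned IDR of 0.01 equals the authors' threshold and gave no value. The number of peaks was 215 to 253 in the replicate lists alone, 163 at an IDR of 0.001 and 1252 at 0.05. The number of more frequent 6-base words was 259 to 282 in the replicate lists, 211 at an IDR of 0.001 and 153 with GC-matched windows; the cause was not tested. The number of gene lists with a lower share was 2 when each peak counted for its nearest start only, against 4; the cause was not tested. The share on chromosome III was 16.3% to 16.996% in the replicate lists and no longer passed the threshold; the cause was not tested. The word TATAAA, less frequent in peaks, reversed with GC-matched windows (0.56 percentage points above background); the cause was not tested. Direction and call were kept for the share near starts (12 alternatives, 42.5% to 78.9%), the replicate overlap (3, 49.8% to 61.4%), the upstream share (3, 54.9% to 65.2%), the GC difference (4, 11.5 to 14.3 points) and chromosomes V and X (3 each). Ribosomal protein, respiratory chain, tRNA, snoRNA, chemoreceptor and piRNA genes kept theirs under 12 of 12 alternatives, as did the 5 named words. Lists with a higher share numbered 6 to 10. Read depth, which the lists do not give, limits which weak sites could be seen. No paired analysis was possible because the labels give a single group.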

Other observations

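The test of signal by kind of gene was chosen after the data were seen; positions by kind of gene and trans-spliced leader genes were looked up afterwards and not tested. Peaks near ribosomal protein genes were not only frequent but strong. Their median signal was 131.6 (19 peaks), against 85.4 for the other 532, a mean difference of 0.65 on the log2 scale (SD 0.77 and 0.80; permutation test, adjusted p = 0.0084 over 4 kinds of gene). Peaks near tRNA genes (84 peaks, median 86.1), snoRNA genes (44, 99.3) and snRNA genes (17, 83.4) did not differ from the rest at the threshold (adjusted permutation p = 0.60, 0.17 and 0.52). Upstream of the start lay 25 of 84 summits at tRNA genes (29.8%), 36 of 44 at snoRNA genes (81.8%), 10 of 17 at snRNA genes (58.8%) and 18 of 19 at ribosomal protein genes (94.7%), against 82.5% of the summits near any protein-coding start. Among trans-spliced leader genes, 5 of 18 SL2 genes (sls-2) and 0 of 12 SL1 genes (sls-1) had a peak. Repeated sequence at these genes was not measured, so the 0 of 12 cannot show that SL1 genes are unbound. With the removed peaks put back, 18 of 129 genes annotated as snRNA had a peak, against 17. Whether the added gene was an SL1 gene was not looked up.

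The frequent peaks at tRNA, snoRNA, snRNA and ribosomal protein genes could have technical sources; the tests of GC content and of shared reads were fixed before their values were seen. GC content around the start as the whole cause was argued against for ribosomal protein genes. In a logistic model with GC content within 250 bp of the start and its square, their odds ratio was 15.8 (95% interval 9.11 to 27.2). It was 20.5 without these terms. Their summits lay at a median position of −294 bp, so the model missed the GC content at many of these summits, which stays open. Reads shared between tRNA copies stay open. Of 22 tRNA genes with only unique 31-base words, 0 had a peak (upper 95% limit 15.4%). Their odds ratio was 1.82 (95% interval 0.110 to 30.0, with 0.5 added to each count). All 99 tRNA genes with a peak were among the 590 with some repeated 31-base words (16.8%, exact 95% interval 13.9 to 20.04). The tRNA genes with and without repeated words were not tested against each other. A signal common to highly transcribed genes stays open as well, since no animals without the tag and no expression values were analysed here. A test on vitellogenin, collagen, myosin heavy chain and major sperm protein genes (1 of 197 with a peak, 0.508%, upper 95% limit 2.80%) was run and then set aside, because their high transcription was assumed and not measured.

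Many peaks fell into families of similar sequence, a grouping chosen after the data were seen, as were the tests by family: 34 families held 167 peaks (30.3%), and the 6 largest other than those of tRNA, snoRNA or snRNA genes held 59. The limit set in advance for sequence alone as the cause was 50% of the families' genome copies. For the 6 families together the share was under it. A peak was present at 56 of 1443 copies (3.88%, exact 95% interval 2.94 to 5.01). Without the 2 families with the most copies it was 45 of 238 (18.9%, 14.1 to 24.5). These shares cannot decide on sequence alone, since a repeated copy may lack a called peak when reads cannot be placed there. Taken singly, 4 families had upper limits of at most 23.3%. The 2 others had 13 of 36 (36.1%, upper limit 53.8%) and 10 of 28 copies (35.7%, 55.9%), which pooled gave 23 of 64 (35.9%, 48.9%). For these 2, sequence alone stays open by the limit as well. Reads shared between near-identical copies stay open as well, since the median share of repeated 31-base words in the windows of these 59 peaks was 48.5%, between the limits set in advance. Mean GC content differed by 1.70 percentage points between copies with and without a peak when compared within families (two-sided permutation p = 0.0016). Copies with a peak were the more repeated in 2 of the 6 families. Over all copies, the median share of repeated words was 56.7% with a peak and 48.5% without.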
